A study of Mus musculus with 8 samples.

How the data were processed

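Total RNA from bone marrow macrophages was extracted with Trizol and cleaned on columns, and biotin-labelled cRNA was hybridised to Illumina mouse beadchips, per the labels' protocols. The authors deposited a table of probe intensity on a linear scale, with 45281 probes and 8 arrays. All 8 columns share the same lowest value, quartiles, median and highest value, as after quantile normalization between arrays. The lowest value was 68.1, with no negative values. The software and the background treatment are not given in the sources used here. A second table with 8 per-sample columns was not used, because its column names match no label. Libraries were grouped by the genotype in the labels, 4 as wild type (WT) and 4 as Vav1 knockout (KO), and numbered as in the sample titles.

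Gene names came from the platform annotation, with symbols looked up by gene identifier in a RefSeq table of assembly GRCm38.p6. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and no gene was named from a probe with several. The update changed 0 symbols, and 78 were kept as annotated because their identifier was not matched. The RefSeq table was used for names, chromosomes and neighbouring genes only.

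Values were background corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and put on the log2 scale. The offset pulls fold changes of dim probes toward 0. Probes with an intensity of at least 100 on at least 4 of the 8 arrays were kept, which left 13479 probes and 7982 named genes. A gene was represented by its probe with the highest mean. Genes differing between the labels were tested with lmFit and eBayes in a model of 2 groups, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. Intensities in the text are the deposited values, and fold changes are on the corrected log2 scale. The plan had been to use neqc on unnormalized signals with detection p-values. Because the usable table was already normalized and has no detection p-values, normexp and the intensity minimum replaced them.

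The design, the 41 gene lists (30 of pathways and macrophage functions, 11 of cell type markers), the rule for named genes and most alternative settings were written before the data were examined. The result of 1 list is not reported here. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. The rule named Vav1 first, then genes past the threshold with full separation of the labels or, where fewer than 6 passed in a direction, the 6 with the smallest p as values that did not pass. It also named Vav2, Vav3, Adgre1, Xist and Ddx3y, and members past the threshold of each list. Unnamed and predicted genes were to be skipped, and 0 were met. Other genes named from the lists are their brightest measured members or were chosen after their values were seen. Absolute fold changes near Vav1 were compared by permuting gene positions 10000 times, one-sided.

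The fit was tested on simulated data and on the real arrays with known changes added to 50 probes per fold size. On simulated arrays with the measured spread, 60% of 2-fold and 88% of 4-fold changes were recovered, with 6 false calls. Alternatives covered the background offset, log2 values without correction, the filter, the variance model, array weights, a block for the replicate number, Xist as a covariate, the threshold, the gene representative and leaving out each library in turn. Arrays were compared by Pearson correlation over the kept probes. Figures were drawn with matplotlib 3.10.9.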

Results

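Gene expression was measured in macrophages grown from mouse bone marrow, on 8 Illumina beadchip arrays. The labels give 4 libraries as wild type (WT 1 to 4) and 4 as Vav1 knockout (KO 1 to 4). Vav1 is a signalling protein of blood cells. The design asks how macrophage expression differs between Vav1-deficient and wild-type mice. Mice were 7 to 12 weeks old, of both sexes, on a C57BL/6 background per the labels. Nothing in the labels says which libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. The values were already normalized to a common distribution, with a median probe intensity of 86.2 and a highest intensity of 26278 on each array. For arrays, the number of libraries limits the precision.

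The targeted gene did not follow the labels. The array has 1 Vav1 probe, and its intensity was high in the libraries labelled WT 1 (1825), WT 2 (1642), KO 1 (1805) and KO 2 (1699). It was low in the libraries labelled WT 3 (267), WT 4 (384), KO 3 (308) and KO 4 (288). The lowest of the high values was 4.27 times the highest of the low values. The lowest value still lay above 86.8% of all probes on its array. The mean intensity was 1025 ± 841 (SD, n = 4) in the libraries labelled knockout and 1030 ± 818 (SD, n = 4) in those labelled wild type. The log2 fold change was -0.05 ± 0.87 (SE), with an adjusted p of 0.981 from limma. Whether the probe lies inside the deleted part of the gene is not given in the sources used here. Because the targeted gene goes against 4 of the labels, every direction in the text is that of the libraries labelled knockout against the libraries labelled wild type, and no library was moved to another group.

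**Figure D1:**
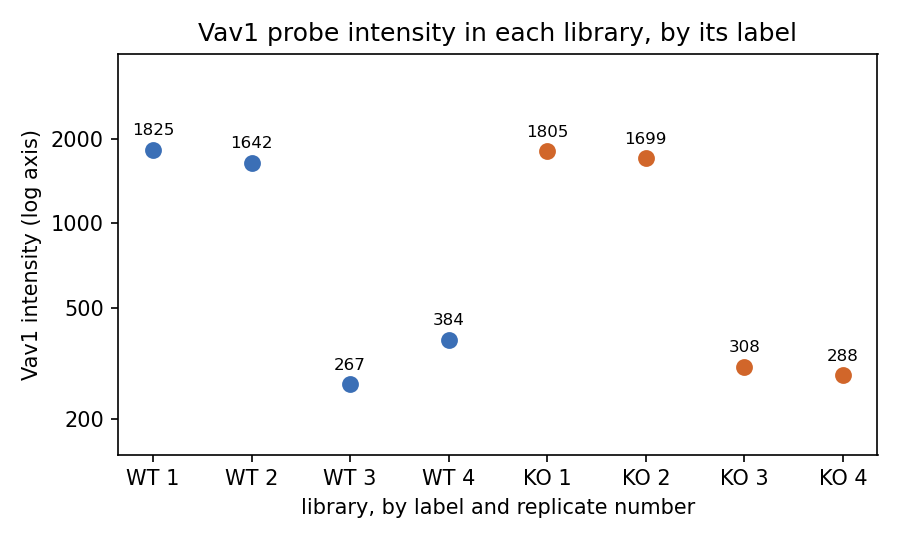
Intensity of the Vav1 probe (log axis) in each library, placed by its label and replicate number, 1 point per library. The libraries numbered 1 and 2 of both labels sit between 1642 and 1825, and those numbered 3 and 4 of both labels sit between 267 and 384.

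Other genes parted the 8 libraries in the same way. Fcer1g, the common gamma chain of Fc receptors, read 15634 to 17180 in the libraries numbered 1 and 2 of both labels and 83.9 to 96.4 in those numbered 3 and 4. H2-Aa, the alpha chain of an MHC class II molecule, read 1571 to 1804 against 80.4 to 86.7 in the same libraries. Myo1f, a leukocyte class I myosin, read 3257 to 5391 against 505 to 823. Hal, which encodes histidine ammonia lyase, went the other way, from 91.5 to 101 in the libraries numbered 1 and 2 to between 2862 and 3815 in those numbered 3 and 4. These genes were chosen after their values were seen. Fcer1g, H2-Aa and Myo1f have 1 kept probe each, and Hal has 2, of which the brightest is given. The low values of Fcer1g and H2-Aa lay near the median probe intensity of 86.2. Whether such gaps reflect transcript levels or sequence differences under the probe was not tested. For each of the 7981 genes tested besides Vav1, the 8 values were ranked and the gap between the 4 lower and the 4 higher was measured. It was at least 2-fold in 28 genes, of which 27 set the same 4 libraries apart as Vav1 did and 0 set the labelled genotypes apart.

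**Figure D2:**
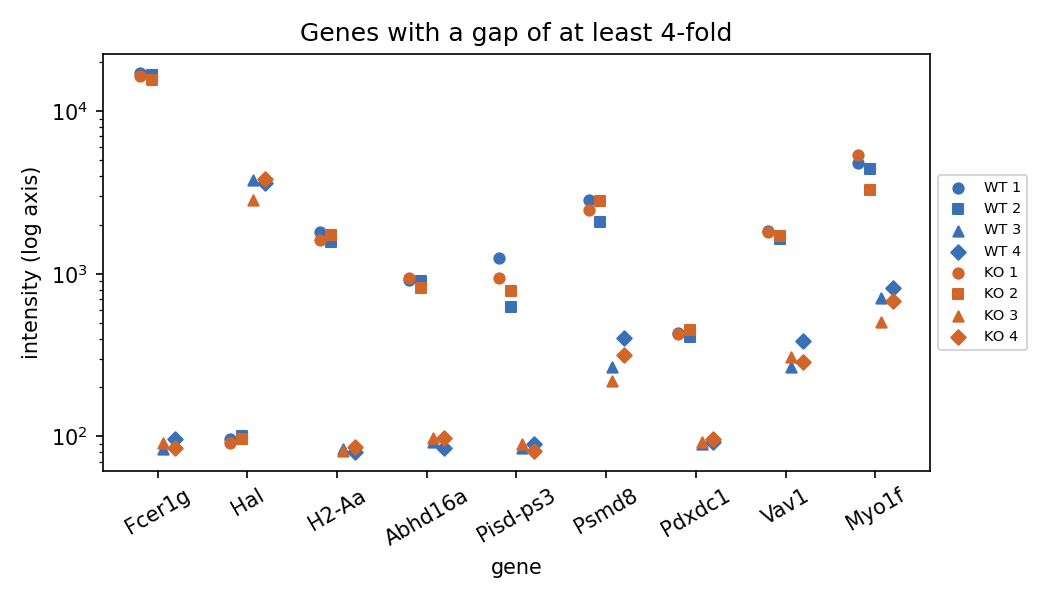
Intensity (log axis) of the 9 genes with a gap of at least 4-fold between the 4 lower and the 4 higher libraries, with colour for the label and marker shape for the replicate number. In each of the 9 genes the libraries numbered 1 and 2 of both labels lie on one side and those numbered 3 and 4 on the other.

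Between the labelled genotypes, no gene passed the test. Of 13479 probes, 0 were higher and 0 were lower in the libraries labelled knockout at an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.795. At an unadjusted p under 0.05 there were 44 probes, 18 higher and 26 lower, where the 35 splits of these arrays into 4 and 4 gave a median of 247. In 91 of the 7982 genes (1.14%) the 4 libraries of 1 label lay all above or all below the other 4, where chance gives 2.86%. The median standard error of a log2 fold change was 0.17, and the median 95% interval reached 0.39 on either side. In a test with known changes added to these arrays, 52% of 2-fold changes and 94% of 4-fold changes were recovered, and 10% of 1.5-fold changes. Without the library labelled WT 4 these shares were 90%, 100% and 56%. All fold sizes were added in the same run, on the corrected log2 scale, to the libraries labelled knockout. The offset did not pull these changes toward 0, as it does for dim probes. The shares may therefore overstate how often a real change in intensity would be found. If libraries were exchanged between the labels, these shares do not tell whether a genotype difference would have been found.

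The genes with the smallest p are given as values that did not pass, each with an adjusted p of 0.795. Higher values in the libraries labelled knockout were those of Gmppb (log2 fold change 0.39 ± 0.15 SE), which makes GDP-mannose, Cog4 (0.63 ± 0.25), a Golgi tethering subunit, and Nop2 (0.28 ± 0.11), an rRNA methyltransferase. Bmx, a Tec family kinase, was at 0.41 ± 0.17, Hltf, a DNA translocase, at 0.43 ± 0.18, and Ambra1, a regulator of autophagy, at 0.33 ± 0.14. Lower values were those of Ninl (-0.37 ± 0.13), a centrosomal protein, Atl3 (-0.36 ± 0.13), which shapes the endoplasmic reticulum, and Eif3j1 (-0.49 ± 0.18), a translation initiation factor subunit. Rpap1 was at -0.28 ± 0.11, Nudt5, an ADP-sugar hydrolase, at -0.41 ± 0.16, and the nucleoporin gene Nup98 at -0.29 ± 0.12. Kept probes of a gene disagreed in direction for Nup98, where 1 of 2 shared the one given, and for Atl3, where 2 of 3 did. Without the library labelled WT 4, Cog4 was at 0.37, Hltf at 0.28, Ambra1 at 0.22, Eif3j1 at -0.32 and Nudt5 at -0.26. Several of these were dim. Gmppb read 123 ± 8.0 (SD, n = 4) in the libraries labelled knockout and 99.8 ± 12.1 (SD, n = 4) in those labelled wild type. Ninl read 96.6 ± 5.15 (SD, n = 4) and 119 ± 12.6 (SD, n = 4). The brightest, Nudt5, read 482 ± 29.9 (SD, n = 4) and 644 ± 145 (SD, n = 4).

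The Vav1 relatives did not pass the test. Vav2 read 641 ± 118 (SD, n = 4) in the libraries labelled knockout and 668 ± 43.0 (SD, n = 4) in those labelled wild type, with a log2 fold change of -0.08 and an adjusted p of 0.845. Vav3 read 1108 ± 41.5 (SD, n = 4) and 1095 ± 109 (SD, n = 4), with a log2 fold change of 0.02 and an adjusted p of 0.942. Adgre1, which encodes the macrophage surface protein F4/80, read 7540 ± 815 (SD, n = 4) and 8421 ± 2480 (SD, n = 4), with a log2 fold change of -0.12 and an adjusted p of 0.824. This direction was shared by 2 of its 3 kept probes. The remaining probe read 82.0 in WT 4 against 211 to 841 in the other libraries, while the brightest read 11859 against 6026 to 8360. The directions of Vav3 and Adgre1 turned without the library labelled WT 4, to -0.021 and 0.06, and Vav2 was at -0.037. Xist, the RNA that silences 1 X chromosome in female cells, was read on each of the 8 arrays, between 911 and 5378, with a log2 fold change of -0.43 ± 0.50 (SE) and an adjusted p of 0.795, and -0.038 without WT 4. The Y-linked genes Eif2s3y, Kdm5d and Uty read at most 100, 86.5 and 128 on any array. These values show no clear signal of male cells in any library, although the labels give mice of both sexes. No probe carried the name Ddx3y.

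The library labelled WT 4 stood apart from the other 7. Its correlations with them over the tested probes were 0.839 to 0.901, while the other 7 correlated with each other at 0.971 to 0.996. In that library, 19.4% of probes lay more than 2-fold from the mean of the others, against 0.3% to 0.7% in each other library. Plin2, which coats lipid droplets, read 102 in it against 1063 to 2180 in the other 7, Gpx1, a glutathione peroxidase, 754 against 7319 to 12146, and Apoe, a lipid carrier, 210 against 740 to 2363. Clec7a, the beta-glucan receptor Dectin-1, read 10792 against 3196 to 5844. Without that library, 0 probes passed and 49 had an unadjusted p under 0.05, while the median standard error fell to 0.12. This leaves WT 1, WT 2 and WT 3 against KO 1, KO 2, KO 3 and KO 4. Genes that part the numbers 1 and 2 from 3 and 4 are then no longer balanced between the labels. Values without WT 4 therefore differ by more than the loss of an outlying library. Over the other 7 libraries, the mean correlation was 0.981 within a label and 0.984 between labels.

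**Figure D3:**
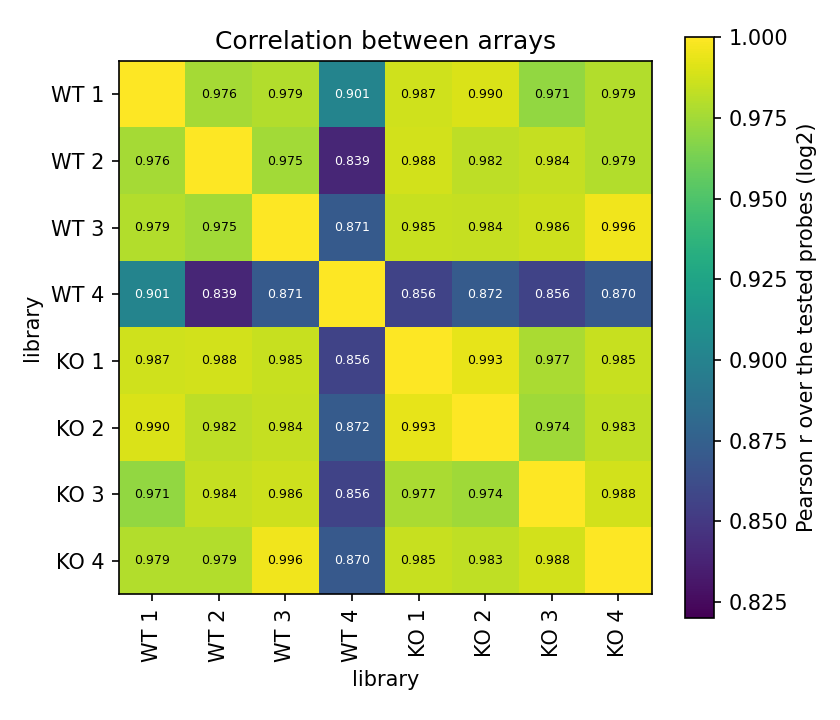
Pearson correlation of log2 intensity over the 13479 tested probes for each pair of libraries, in order of label and replicate number, with the colour scale from 0.82 to 1. WT 4 correlates at 0.839 to 0.901 with the others, and the other 7 at 0.971 to 0.996 with each other.

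Some macrophage genes were bright under both labels, and others were dim. Of 18 measured genes of macrophage identity, 0 passed, 12 had a higher and 6 a lower value in the libraries labelled knockout, and the median log2 fold change was 0.14 (adjusted p = 0.148), and 0.06 without the library labelled WT 4. Lyz1, a lysozyme, read 18399 ± 3919 (SD, n = 4) in the libraries labelled knockout and 19532 ± 5731 (SD, n = 4) in those labelled wild type. Sirpa, an inhibitory receptor, read 15788 ± 1779 (SD, n = 4) and 15514 ± 961 (SD, n = 4). Csf1r, the receptor for the main macrophage growth factor, read 4698 ± 601 (SD, n = 4) and 3443 ± 1245 (SD, n = 4). The log2 fold change of Csf1r was 0.52, and 0.295 without WT 4, and that of Lyz1 was -0.06, and 0.08 without it. Itgam, an integrin chain, had mean intensities of 166 and 154, and Cebpa, a myeloid transcription factor, 105 and 98.0. Of 21 lysosomal genes 0 passed, with a median of 0.03 (adjusted p = 0.487). Among them Gpnmb read 22899 ± 3636 (SD, n = 4) and 22357 ± 3031 (SD, n = 4). Complement genes had a median of 0.15 (adjusted p = 0.328). C1qc, a chain of C1q, read 5344 ± 1260 (SD, n = 4) and 3603 ± 2289 (SD, n = 4), and 1057 in WT 4 alone. Iron handling genes had a median of 0.04 (adjusted p = 0.592) and scavenger receptors -0.12 (adjusted p = 0.666). The medians without WT 4 were 0.06 for complement, 0.01 for iron handling and 0.03 for scavenger receptors, the last with its direction turned. These and the following adjusted p-values of gene lists are from camera, the competitive set test of limma, over 36 lists.

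Lists of the cytoskeleton, adhesion and receptor signalling did not pass. The 18 genes of the actin cytoskeleton and podosomes had a median log2 fold change of 0.02 (adjusted p = 0.526), and 0.03 without WT 4. Arpc5, a subunit of the Arp2/3 complex, read 10967 ± 302 (SD, n = 4) in the libraries labelled knockout and 11465 ± 272 (SD, n = 4) in those labelled wild type. Integrins and adhesion genes had a median of 0.14 (adjusted p = 0.180), and 0.03 without WT 4. The 19 genes of Fc receptor and ITAM signalling had the lowest adjusted p of all lists, 0.0588, with 13 higher and 6 lower values and a median of 0.23. The adjusted p was 0.724 with an estimated correlation. Tyrobp, the adaptor DAP12, was at 0.27 ± 0.22 (SE), Btk, a Tec kinase, at 0.51 ± 0.34, and Fcgr1 at 0.29 ± 0.19. Without WT 4 these were 0.05, 0.13 and 0.17. Among the 6 lower values, Lcp2 was at -0.30 and Clec7a at -0.25, and at -0.015 and 0.08 without WT 4. Fcer1g, which parted the libraries by number, was also among them at -0.065, and at -1.35 ± 2.57 (SE) without WT 4. In WT 4 this list lay 0.59 below the other 7 libraries (median log2 difference -0.59). Without WT 4 the median between the labels was 0.06, with an adjusted p of 0.0389, and an adjusted p of 0.433 with an estimated correlation. NADPH oxidase genes had a median of 0.38 (adjusted p = 0.278), and -0.025 without WT 4, where the list lay at -1.24 relative to the other 7.

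Lists of activation and immune response did not pass. Inflammatory cytokines and NF-kB targets had a median of -0.028 (adjusted p = 0.759), Toll-like receptors and adaptors 0.04 (adjusted p = 0.547), and interferon-stimulated genes 0.05 (adjusted p = 0.388). Ccl4, a chemokine, read 8622 ± 1239 (SD, n = 4) in the libraries labelled knockout and 9698 ± 2142 (SD, n = 4) in those labelled wild type. Its log2 fold change was -0.16, and -0.014 without WT 4, where it read 12834 against 7687 to 10380 in the other libraries. Classical activation genes had a median of -0.06 (adjusted p = 0.675) and alternative activation genes 0.01 (adjusted p = 0.526). Mrc1, the mannose receptor, read 5399 ± 1211 (SD, n = 4) and 5276 ± 308 (SD, n = 4). MHC class II and antigen presentation genes had a median of -0.007 (adjusted p = 0.513), with 9 higher and 9 lower values. Leaving out WT 4 gave a median of -0.154 and turned the direction of camera. Members of this list that parted the libraries by number were then at -0.79 (H2-Aa), -0.515 (H2-Ab1), -0.36 (H2-Eb1) and -0.33 (Cd74). Without WT 4 those numbers are unbalanced between the labels. In that list the standard error was 1.58 for H2-Aa and 0.79 for H2-Ab1, against the median of 0.17 over genes. Chemokines had a median of -0.014 (adjusted p = 0.943), chemokine and growth factor receptors -0.017 (adjusted p = 0.526), and matrix proteases and matrix -0.06 (adjusted p = 0.686). For these 3 lists the medians without WT 4 were -0.08, 0.10 and 0.02, those of the last 2 with their sign turned. They were -0.08 for inflammatory cytokines, 0.02 for Toll-like receptors and 0.07 for alternative activation.

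Metabolic, stress and growth lists did not pass either. Cholesterol efflux and LXR targets had a median of 0.40 (adjusted p = 0.209) and cholesterol biosynthesis 0.22 (adjusted p = 0.148). Without WT 4, these medians were 0.01 and 0.02. PPAR targets and lipid droplets had a median of 0.04 (adjusted p = 0.622), glycolysis and hypoxia response 0.16 (adjusted p = 0.148), and oxidative phosphorylation 0.02 (adjusted p = 0.388). Without WT 4 these were 0.007, 0.05 and 0.004. Lpl, lipoprotein lipase, read 18964 ± 2898 (SD, n = 4) in the libraries labelled knockout and 22280 ± 4462 (SD, n = 4) in those labelled wild type. Cell cycle genes had a median of 0.14 (adjusted p = 0.148), with 13 higher and 9 lower values, and 0.06 without WT 4. Top2a, a topoisomerase of dividing cells, was at 0.84 ± 0.62 (SE) and read 114 in WT 4 against 478 to 973 in the other 7 libraries; without WT 4 it was at 0.13. Antioxidant response genes had a median of -0.017 (adjusted p = 0.771), the unfolded protein response -0.028 (adjusted p = 0.666), immediate early and heat shock genes -0.07 (adjusted p = 0.705), p53 targets -0.007 (adjusted p = 0.786), and ribosomal proteins 0.13 (adjusted p = 0.278). Ribosomal proteins and immediate early and heat shock genes turned in median without WT 4, to -0.007 and 0.07, and antioxidant response genes were at -0.035.

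**Figure D4:**
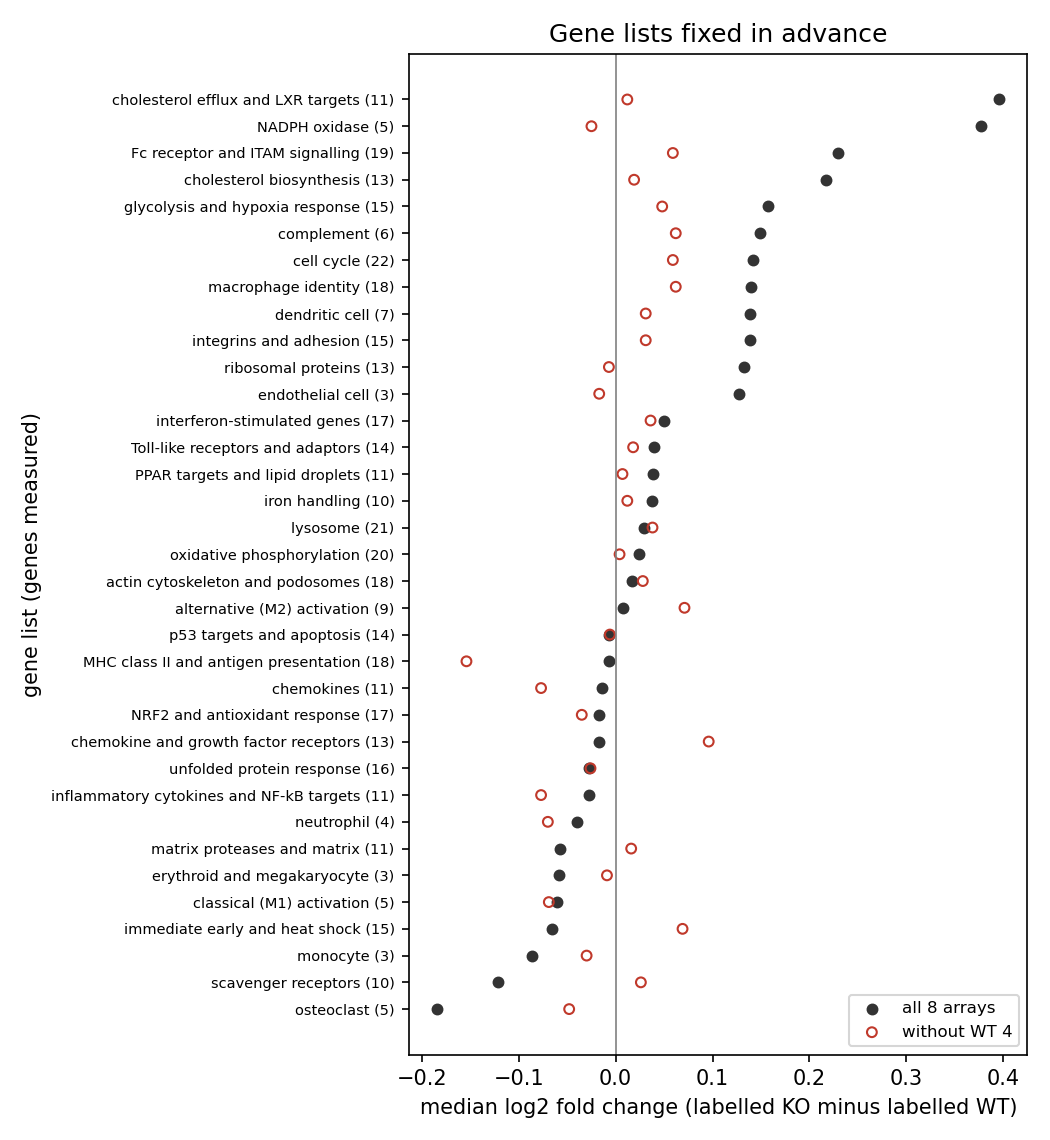
Median log2 fold change, libraries labelled knockout minus libraries labelled wild type, of 35 of the 36 gene lists tested, with all 8 arrays (filled) and without the library labelled WT 4 (open). The number of genes measured is in parentheses. NADPH oxidase genes lie at 0.38 with all arrays and at -0.025 without WT 4.

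Markers of other cell types were mostly dim and did not pass. Monocyte markers had a median of -0.09 (adjusted p = 0.979), neutrophil markers -0.04 (adjusted p = 0.903), and dendritic cell markers 0.14 (adjusted p = 0.207). Erythroid and megakaryocyte markers had a median of -0.06 (adjusted p = 0.686), osteoclast markers -0.18 (adjusted p = 0.526), and endothelial markers 0.13 (adjusted p = 0.526). Without WT 4 these 6 medians were -0.03, -0.07, 0.03, -0.009, -0.048 and -0.017, the last with its sign turned. The neutrophil gene S100a8 read 205 ± 15.3 (SD, n = 4) in the libraries labelled knockout and 214 ± 41.4 (SD, n = 4) in those labelled wild type. The monocyte gene F13a1 read 105 ± 5.98 (SD, n = 4) and 114 ± 13.4 (SD, n = 4). Some list members were bright. S100a4, from the monocyte list, read 1266 ± 677 (SD, n = 4) and 858 ± 490 (SD, n = 4). Cst3, from the dendritic cell list, read 8430 ± 933 (SD, n = 4) and 7777 ± 2775 (SD, n = 4). Tfrc, from the erythroid list, read 8336 ± 2438 (SD, n = 4) and 9058 ± 1920 (SD, n = 4). The lists for T cells, B cells, NK cells, stromal cells and mast cells had fewer than 3 measured genes and were not tested. Their measured genes gave median log2 fold changes of 0.41 for T cells, -0.19 for B cells, -0.57 for NK cells, -0.21 for stromal cells and 0.04 for mast cells, basophils and eosinophils. Without WT 4 these were -0.009, 0.03, -0.07, -0.08 and -0.03, so the signs for T cells, B cells and mast cells turned. The B cell gene Cd22 read 99.2 ± 8.4 (SD, n = 4) and 113 ± 32.3 (SD, n = 4). Il7r, from the T cell list, was bright at 3630 ± 637 (SD, n = 4) and 3714 ± 536 (SD, n = 4).

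Over the 41 lists, 0 members passed over all probes tested and 0 passed when adjusted over the list alone. Of the 36 tested lists 0 passed, and 8 had an unadjusted p under 0.05, all 8 toward higher values in the libraries labelled knockout. With an estimated correlation 0 lists passed, and with fry, which tests each list by itself, 0 passed (lowest adjusted p = 0.386). In 10 lists the median, the mean and the direction of camera differed in sign. Without WT 4 the camera direction turned in 7 lists, and 3 lists passed with an adjusted p of 0.0389 each, namely Fc receptor signalling, cell cycle and macrophage identity, with medians of 0.06. With an estimated correlation their adjusted p-values were 0.433, 0.460 and 0.433, and 14 of the 35 splits of these 7 arrays gave at least 3 lists.

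Genes near Vav1 on chromosome 17 were compared with all others, since a targeted allele can carry flanking sequence of another strain. Within 5 Mb, 36 tested genes had a median absolute log2 fold change of 0.15 between the labels, against 0.15 elsewhere (permutation p = 0.469). Within 20 Mb, 127 genes had 0.16 (permutation p = 0.245). In both windows 0 genes passed and 0 had an unadjusted p under 0.05 in limma, where elsewhere 27 did. The comparison follows the labels, which the Vav1 probe did not. If libraries were exchanged between the labels, it could not show a segment carried with the targeted allele.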

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

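The tests of the Vav1 pattern were chosen after its values were seen, as was the look at marker lists with fewer than 3 measured genes, while the other tests of the library labelled WT 4 were fixed before. Among 36 checks of 4 libraries each, a library lay far from the other 3 of its label in 2, and chance gives about 1 in 20. The mean correlation of WT 4 with the other 7 arrays was 0.867, where the other libraries labelled wild type had 0.960 to 0.969. The intensity of Eif3j1 in WT 4 was 162, against 105 to 111 in the other 3 libraries labelled wild type.

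WT 4 was lower than all other 7 libraries in 184 of 416 measured list genes and higher than all in 121, where chance puts 25% outside; the list medians furthest below the other 7 were NADPH oxidase (-1.24), cholesterol biosynthesis (-0.86) and cholesterol efflux and LXR targets (-0.78). No tested marker list of another cell type met both conditions set in advance. The highest median, 0.546 for 3 erythroid and megakaryocyte genes, was over the 0.5 set, but its 95.7 percentile of matched random lists fell short. Of these genes, Tfrc and Pf4 read at least 5895 and 3485 in the other 7 libraries. Epor read 100 in WT 4 and lay within the 85.4 to 109 of the others. Cells of another type stay open, since lists with fewer than 3 measured genes were not ranked. Of the 8 genes in those lists 3 lay above the other 7 libraries, Prf1 at 548 against 117 to 230, Cd22 at 160 against 88.3 to 108 and Acta2 at 218 against 109 to 132, while Cd28 lay below, at 85.3 against 602 to 1032. RNA degradation or uneven amplification remains open too: the deviations of 2 probes of a gene correlated at 0.313 across 2763 genes (95% interval 0.278 to 0.346). Genes are not independent replicates, and the other libraries gave 0.330 to 0.421. These also lay under the 0.5 set in advance for this test, so that cutoff does not set WT 4 apart. Their deviations had a far smaller spread (SD 0.218 to 0.324 against 0.864). Probe noise of that smaller size would not by itself keep the correlation in WT 4 so low. The deviations of the other libraries were taken from means that include WT 4. Their spread and their correlations are therefore not free of that library, and probe noise was not tested apart from it.

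The Vav1 signal was high in 2 libraries labelled knockout and low in 2 labelled wild type. A probe outside the deleted part stays open: the highest intensity was 6.83 times the lowest, but 7 genes that were not targeted parted the same libraries by a larger gap. An exchange of libraries between the labels stays open as well, since with 4 high and 4 low values the 2 displaced libraries under each label are equal in number by arithmetic. Separate cohorts of mice or cultures for the numbers 1 and 2 and the numbers 3 and 4 cannot be told apart from an exchange by Vav1 alone, since the 4 highest intensities were all 4 from libraries numbered 1 or 2. Those 4 libraries are also the first 4 in the order of the sample records. The number is therefore not the only attribute that this split follows. Genotype itself was not tested here beyond this probe, and the libraries were not regrouped by it.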

How the results depend on the processing

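The normexp offset of 16, the intensity minimum of 150 and the block of numbers 1 and 2 against 3 and 4 were chosen after seeing the data; the rest were planned. Under 20 alternative settings the counts of genes higher and lower in the libraries labelled knockout stayed at 0 and 0, with a lowest adjusted p of 0.505 in limma. Unadjusted calls ranged from 9 probes without KO 4 to 549 without WT 2 with the same filter, and were 938 with no filter. Of 298 values of named genes, 286 kept their direction and 0 passed.

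The count of gene lists past the threshold, 0 in the report, was 1 with log2(value + 16), 1 with the authors' values on the log2 scale, 1 with an intensity of at least 150 on all 8 arrays, 4 with array weights, 2 with Xist as a covariate and 2 with the mean of all kept probes. It was 0 to 3 when a library was left out: 3 without WT 4, 2 without WT 3 or KO 3 and 1 without KO 1. It was 0 with fry, and 0 with an estimated correlation in the report's fit and in each of the alternatives so tested (lowest adjusted p = 0.363). The adjusted p of Fc receptor signalling from camera lay near the threshold (0.0588), and was 0.0190 to 0.0496 in the alternatives where this list passed. The cause of these and the other moves was not tested.

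Vav1's log2 fold change was 0.009 with Xist as a covariate and -0.56 to 0.41 when a library was left out, since each removal unbalances high and low values. Vav3 turned to -0.025 and Adgre1 to 0.014 with Xist as a covariate, and Adgre1 to 0.021 with array weights. Leaving out a library gave -0.268 to 0.058 for Adgre1, -0.021 to 0.088 for Vav3 and -0.184 to 0.031 for Vav2; the cause was not tested.

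Deviations of same-numbered libraries correlated at 0.46, -0.17, 0.14 and 0.13; as 1 of the 4 was negative, the numbers were not treated as pairing the libraries. With the replicate block, 0 genes passed and 1 list did, Fc receptor signalling (adjusted p = 0.0492, and adjusted p = 0.692 with an estimated correlation), and Vav1 was at -0.05. Windows of 2 and 40 Mb around Vav1 gave medians of 0.15 and 0.16. Detection p-values, neqc, median centring and a chip block were not run, since the values used hold neither detection p-values nor unnormalized signals and name no chip. The lower quartile of intensity (81.2) lay near the lowest value (68.1), so dim genes limit what can be seen.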

Other observations

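The tests over splits of gene lists and of probes at an unadjusted p, and those of genes whose values part into 4 and 4, were chosen after the result was seen. Further genes that parted the libraries numbered 1 and 2 from those numbered 3 and 4 are given as examples picked after their values were seen, and no function was tested for enrichment among them. H2-Ab1 read 999 to 1418 in the first set and 203 to 345 in the second, H2-Eb1 488 to 626 and 180 to 215, and Cd74, the invariant chain, 1484 to 1927 and 311 to 621. Cd48, a ligand on leukocytes, read 324 to 458 and 85.3 to 107, Pdpn, podoplanin, 416 to 455 and 109 to 124, and Itgb7, an integrin chain, 194 to 242 and 82.1 to 98.5. Of the 27 genes besides Vav1 with a gap of at least 2-fold that parted the libraries so, 22 were higher in the first set and 5 in the second. Atp10d, a lipid flippase, was among the 5, at 108 to 116 in the first set and 317 to 553 in the second. Whether these reflect transcript levels or sequence differences under the probe shown was not tested. H2-Ab1 and Cd74 have 3 kept probes each, and the values given are of the brightest only.

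Such genes were over-represented on chromosome 17, which carries Vav1 and the MHC: without Vav1, 6 of 424 tested genes there (1.42%) had a gap of at least 2-fold, against 21 of 7546 elsewhere (0.278%), with a two-sided Fisher's exact p of 0.00249. All 6 (Myo1f, H2-Aa, H2-Ab1, H2-Eb1, D17H6S56E-5 and Abhd16a) lay 22.2 to 23.7 Mb from Vav1, and 0 of the 127 tested genes within 20 Mb had such a gap. Within 40 Mb, a window that takes in these 6, it was 6 of 386 genes (odds ratio 5.68, Fisher's exact p of 0.00154). At 1.5-fold, 1 of the 127 genes within 20 Mb had a gap, 8.9 Mb from Vav1 (odds ratio 1.07). A chromosome segment of another strain around Vav1 stays open, since the 95% interval of the odds ratio within 20 Mb was 0 to 9.13. Co-regulation of MHC class II genes stays open: without the members of the MHC list, 3 of 411 remained, with a Fisher's exact p of 0.113 at 2-fold (0.00161 at 1.5-fold, 0.0348 at 4-fold). Cohorts by replicate number cannot be told apart from the labels being exchanged, since 27 of 28 such genes parted the numbers 1 and 2 from 3 and 4; neighbouring genes are not independent.

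With 0 probes past the threshold between the labels, all 35 splits of the 8 arrays gave as many by arithmetic, which tests nothing. Of these splits, 1 gave any, 163 probes, and it set the libraries numbered 1 and 2 of both labels against those numbered 3 and 4. Without WT 4, where the 35 of 35 is again fixed, the same partition gave 532 probes. This points to a structure of the samples that the labels do not follow; with those numbers as a block, 0 genes passed and the lowest adjusted p was 0.778. Chance cannot be excluded for the 44 probes with an unadjusted p under 0.05 between the labels, since 28 of 35 splits gave as many, the highest other giving 1358. Nor can it for the 49 without WT 4, where 35 of 35 gave as many, with a median of 539 and the highest other at 2113. For gene lists the count of the labels was 0, so that 35 of 35 splits gave as many tests nothing, and the highest other gave 7. Without WT 4, 14 of 35 splits gave at least the 3 lists of the labels, the highest other giving 8, so chance cannot be excluded there either.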
